A study of Cyprinus carpio with 18 samples.

How the data were processed

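Embryos and larvae of common carp (Cyprinus carpio) of the FFRC No.2 strain were sampled at 6 stages, with 3 libraries per stage. Per the labels' protocols, the libraries were strand-specific, made after removal of ribosomal RNA, and sequenced on an Illumina HiSeq X-Ten. The labels number the libraries of a stage 1 to 3 and do not say that they come from separate spawnings. Stages were taken from the labels, and no library was left out.

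The deposited counts are whole numbers of reads assigned to each feature, per the file headers, 1 value per feature and library, with no normalization. The count file of each of the 18 libraries equals the deposited series table in every row. The same table gives RPKM, made by the authors per kilobase of length and scaled to library size. Within a library each deposited RPKM equals its count times 1 constant divided by a length of the feature, and this constant does not follow from the total of assigned counts. What library size the authors used is not given in the sources used here, so RPKM served only for alternatives. Per the submitters' processing notes HISAT2, StringTie 1.3.3b, featureCounts and edgeR were used. Their settings, the genome build and the annotation are not given in the sources used here, so no coordinates are given.

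The tables hold 90808 features, 58294 with an NCBI GeneID and 32514 with a StringTie name (MSTRG) only. By the deposited class, 49264 are protein-coding, 41485 are lncRNAs and 59 are transcribed pseudogenes. Of the lncRNAs 8971 have an NCBI GeneID and the rest have a StringTie name only. Gene names came from the deposited table and from an NCBI table of carp assembly ASM1834038v1, used for names only, in which 36765 GeneIDs were found. A symbol or product name was had for 46317 features. Carp has a duplicated genome, and whether the authors' counting split, shared or dropped reads that fit more than 1 copy is not given in the sources used here. Values of single copies are therefore uncertain in families of near-identical genes, such as histones, hemoglobins, crystallins, titins, keratins, zinc fingers and choriolytic enzymes.

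Library totals ran from 16326813 counts (cleavage replicate 3) to 43270557 (gastrulation replicate 2). The main test was edgeR 4.0.16 in R 4.3.3: features passing filterByExpr (69265, of them 41841 protein-coding and 27368 lncRNAs), TMM factors, 1 coefficient per stage fitted to all 18 libraries, and robust quasi-likelihood F tests. Each stage was tested against the one before, in 5 comparisons, and all stages together in 1 further test. Benjamini-Hochberg adjustment ran over the tested features of a comparison, and features with an adjusted p under 0.05 are said to have risen or fallen. Means and SDs are of CPM with TMM factors over 3 libraries, and log2 changes were computed from the deposited counts by edgeR, with the SE from its fit. Where a stage had no counts, the fold is against 3 counts summed over the stage, and where it had 1 to 3 counts, the ratio has a 95% exact counting interval.

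On counts simulated for larva against hatching, 100 of 69265 features were changed 2-fold and 100 were changed 4-fold. Of these edgeR recovered 29% of the 2-fold and 55% of the 4-fold changes, and among features with over 100 counts 60% and 87.2%. It made 7 false calls. These values hold for the simulated counts only.

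Gene lists were fixed by symbol and product name before the data were examined, as were the main tests, the alternative settings and the rule for named genes. Of 24 lists, mitochondrially encoded genes had no member among the features and 23 were tested in each comparison with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over all lists and comparisons. Of the calls made, 31 were lost with an estimated correlation. Each of these has its p beside it in the report, and every other call held. Product patterns took in some genes outside a list's name, such as homologs of human open reading frames and interferon regulatory factor 2-binding proteins among innate immune effectors (29 features), oocyte zinc finger and zona pellucida-like domain genes among oocyte genes (35 features), repeat-containing and geminin coiled-coil proteins among cell cycle genes (24 features) and phosducin-like genes among eye genes (2 features). An alternative left them out.

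In each comparison the rule for named genes took the 6 named genes with the largest rise and the 6 with the largest fall that passed the test, had a mean of 10 CPM or more in the higher stage and did not overlap between the 3 and 3 libraries, as well as the 2 unnamed or lncRNA features with the largest rise and the 2 with the largest fall. It also took the 4 members of each list with the highest mean CPM, whatever their test. The text names only part of these, 1 result drawn from them is not reported here, and genes that share a name are given with their identifiers.

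Genes detected were those with 10 or more counts after each library was thinned at random to the smallest total. These counts and the lncRNA share of counts were compared by 2-sided exact permutation tests with scipy 1.17.1 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3. The alternative settings were DESeq2 1.42.0, upper-quartile factors, library totals, no filter, a filter of 1 CPM in 3 libraries, an adjusted p under 0.01, a 2-fold minimum, a fit of only the 2 stages compared, the replicate number as a block, each library of the stages compared left out in turn, and limma on log2 of the deposited RPKM plus 1 or plus 0.1. For lists they were fry, an estimated correlation and symbols alone, and for genes detected other count minimums and no thinning.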

Results

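RNA was measured in whole embryos and larvae of common carp, Cyprinus carpio, of the FFRC No.2 strain, a selectively bred farmed variety, at 6 stages with 3 libraries each. The stages were cleavage at 2 hours post-fertilization (hpf), blastocyst at 6 hpf, gastrulation at 12 hpf, organ formation at 20 hpf, hatching at 64 hpf and the larva 1 day post-hatching. The libraries kept strand information and had ribosomal RNA removed, so that both messenger RNAs and long non-coding RNAs (lncRNAs) were counted. Replicates 1, 2 and 3 held 31238862, 24007184 and 16326813 counts at cleavage, 35620823, 34014020 and 34686458 at blastocyst and 18982510, 43270557 and 36598095 at gastrulation. At organ formation they held 20206505, 21170153 and 19624716 counts, at hatching 31234277, 33002831 and 34981183 and in the larva 25476993, 28707423 and 23300076. The chi-square per degree of freedom between libraries of 1 stage was 3.84 or more, so no library was a repeat of another within sampling noise. Per the labels' protocols RNA of a stage was pooled before library construction. The p-values therefore measure only the spread between these libraries, which may be technical.

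Levels are mean CPM (counts scaled to an equal library total) ± SD over the 3 libraries of a stage, and changes are on the log2 scale, later stage minus earlier stage, with their standard error (SE). For a gene without counts at 1 of the stages the fold is a lower bound against a floor of 3 counts summed over the stage. Intervals and floors cover counting error only. The series follows expression from stage to stage, so each stage was compared with the one before. Of 69265 tested features, 64874 (93.7%) differed among the 6 stages (edgeR, adjusted p under 0.05). The 39828 protein-coding genes called most often had their highest mean in the larva (12348 genes), and the 24992 lncRNAs called most often at organ formation (6909 lncRNAs). Of the 41485 lncRNA features in the data 8971 have an NCBI GeneID, and all 32514 features with a StringTie name only are of this class.

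**Figure D1:**
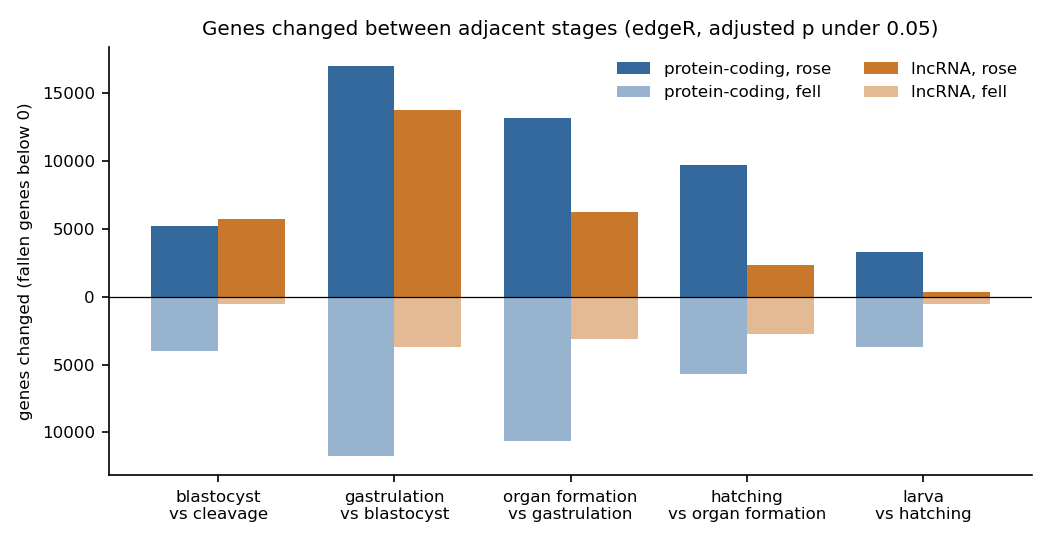
Number of protein-coding genes and lncRNAs that rose (bars above 0) or fell (bars below 0) in each comparison of a stage with the one before, from the edgeR test at an adjusted p under 0.05. The step from blastocyst to gastrulation has the tallest bars, with 16978 protein-coding genes and 13754 lncRNAs that rose, though over all features together the balance turns under the library denominators of the deposited RPKM, and the step from hatching to larva has the shortest bar for lncRNAs that rose (347).

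From cleavage to blastocyst, 19 of 25 tested blastula transcription factors rose. The transcription factor sox19a, which acts in the early neural plate, rose from 0.0751 ± 0.0734 to 34.5 ± 5.76 CPM (log2 change 8.90, SE 0.32, edgeR adjusted p = 1.2e-14). Its copy (LOC109090287) rose from 0.516 ± 0.258 to 51.4 ± 11.7 CPM (edgeR adjusted p = 8.2e-15). Apolipoprotein Eb (LOC109058451), a lipid carrier of the yolk syncytial layer, rose from 1.17 ± 0.3896 to 107 ± 22.97 CPM (log2 change 6.46, SE 0.19, edgeR adjusted p = 9.8e-16). In the other direction, 67 of 152 nuclear genes of oxidative phosphorylation fell, a list whose call was lost with an estimated correlation between genes (adjusted p = 0.08). The gene btg4, of maternal transcript turnover, fell from 655 ± 41.9 to 298 ± 34.1 CPM (log2 change -1.14, SE 0.36, edgeR adjusted p = 0.038). In all, 10962 of 69265 features rose and 4517 fell. Of the lncRNAs, 5734 rose and 541 fell, and of the protein-coding genes 5216 rose and 3970 fell.

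Several of the largest rises were of genes without a single count at cleavage. The gastrula zinc finger gene XlCGF52.1-like (LOC109085259) reached 42.3 ± 10.2 CPM, at least 1246-fold higher. XlCGF8.2DB-like (LOC109112486) reached 36.3 ± 8.32 CPM, at least 1071-fold higher. XlCGF26.1-like (LOC109052311) reached 30.7 ± 6.85 CPM, at least 904-fold higher. The histone H4 methyltransferase KMT5A-like (LOC109068150) rose at least 882-fold to 29.9 ± 4.17 CPM. The HES-7.1-B-like repressor (LOC109102174) rose at least 646-fold to 21.9 ± 3.03 CPM. The unnamed lncRNAs MSTRG.57324 and MSTRG.70617 rose at least 2886-fold to 97.8 ± 24.8 CPM and at least 2228-fold to 75.5 ± 22.3 CPM. All of these had edgeR adjusted p = 2.2e-09 or lower. The largest falls were smaller. OCIA domain-containing protein 1-like (LOC109095460) fell from 15.3 ± 1.43 to 2.91 ± 0.779 CPM (log2 change -2.39, SE 0.25, edgeR adjusted p = 4.8e-07). A gonadal histone H2B (zgc:92591) fell from 14.7 ± 1.41 to 3.57 ± 0.365 CPM (edgeR adjusted p = 3.9e-04). The mitotic kinesin KIF20A (zgc:56231) fell from 614 ± 13.3 to 162 ± 16.4 CPM (log2 change -1.92, SE 0.15, edgeR adjusted p = 5.0e-09). The sialic acid synthesis gene gne fell from 15.01 ± 1.69 to 4.03 ± 1.21 CPM (edgeR adjusted p = 5.4e-08).

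Among blastula transcription factors 19 of 25 tested members rose, 0 fell and 6 did not pass (19 and 0 adjusted over the list alone, camera adjusted p = 3.5e-11). Both copies of the pluripotency factor pou5f3 were already abundant at cleavage and rose less: pou5f3 rose from 203 ± 5.79 to 372 ± 12.03 CPM and LOC109046005 rose from 229 ± 12.6 to 371 ± 35.2 CPM (edgeR adjusted p = 0.0014 or lower). Of the mesendoderm and gastrula patterning genes 23 of 60 tested members rose, 5 fell and 32 did not pass (25 and 6 adjusted over the list alone, camera adjusted p = 5.0e-05). Among them the BMP antagonist chordin (chrd) rose from 0.158 ± 0.1098 to 19.4 ± 7.57 CPM (log2 change 6.81, SE 0.35, edgeR adjusted p = 3.1e-11). The endoderm factor gata6 rose from 0.733 ± 0.996 to 4.49 ± 1.65 CPM (edgeR adjusted p = 0.0048). Of the keratin and epidermis genes 17 of 57 tested members rose, 1 fell and 39 did not pass (19 and 2 adjusted over the list alone, camera adjusted p = 3.9e-05, adjusted p = 0.08 with an estimated correlation). Keratin 18 (LOC109047943), an intermediate filament gene of simple epithelia, rose from 0.664 ± 0.0653 to 66.3 ± 6.28 CPM (log2 change 6.65, SE 0.15, edgeR adjusted p = 9.3e-18). Of the yolk lipid transport genes 5 of 11 tested members rose, 1 fell and 5 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0067). The microsomal triglyceride transfer protein (LOC109108977), which loads lipid onto apolipoprotein B, rose from 0.451 ± 0.0846 to 7.93 ± 2.504 CPM (edgeR adjusted p = 1.1e-04).

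Of the histone genes 104 of 166 tested members rose, 4 fell and 58 did not pass (120 and 5 adjusted over the list alone, camera adjusted p = 1.3e-15, adjusted p = 0.13 with an estimated correlation). The most abundant histone H2A copy (LOC109051002) rose from 2163 ± 111 to 3161 ± 113 CPM (edgeR adjusted p = 0.0029). Of the nuclear oxidative phosphorylation genes 6 of 152 tested members rose, 67 fell and 79 did not pass (8 and 85 adjusted over the list alone, camera adjusted p = 1.9e-21, adjusted p = 0.08 with an estimated correlation). ATP synthase subunit O (LOC109096800) fell from 48.3 ± 1.84 to 23.8 ± 4.24 CPM (log2 change -1.02, SE 0.13, edgeR adjusted p = 4.8e-06). Of the oocyte and maternal genes 5 of 100 tested members rose, 14 fell and 81 did not pass (5 and 14 adjusted over the list alone, camera adjusted p = 5.6e-04, adjusted p = 0.088 with an estimated correlation). That list's median was -0.31 (also -0.31 with genes at their bound) and its mean 0.02, so mean and test differed in sign. The 5 members that rose, named here after their values were seen, were oocyte zinc finger genes (LOC109044852, LOC109072240 and LOC109086123), a zona pellucida-like domain gene (LOC109098176) and npm3, a nucleoplasmin family gene. Of the germ plasm and piRNA genes 1 of 31 tested members rose, 4 fell and 26 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.067 with an estimated correlation), a call that ended without cleavage replicate 1 or 3 or blastocyst replicate 2. Of its members, 1 tudor gene copy (LOC109067922) fell from 242 ± 28.2 to 153 ± 19.8 CPM (edgeR adjusted p = 0.0012). Among cell cycle genes the counts were balanced: 23 of 103 tested members rose, 23 fell and 57 did not pass (25 and 25 adjusted over the list alone, camera adjusted p = 0.26). Camera called none of the remaining lists, and mean and test differed in sign for cell cycle, eye, Hox, cardiac, pancreas, liver, erythroid, muscle, neural, hatching enzymes, stress and innate immunity.

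With the library denominators that the deposited RPKM values imply in place of TMM factors, 7752 features rose and 6396 fell. With limma on RPKM of 34454 features the balance turned: 1821 rose and 6857 fell on log2(RPKM + 1) and 2282 and 5611 on log2(RPKM + 0.1). The count of falls moved with the libraries in the fit and with the filter. It was 2289 without cleavage replicate 2, 2341 without cleavage replicate 3 and 2343 without blastocyst replicate 3. Without gastrulation replicate 1, 2 or 3, a stage not compared here, it was 2573, 2564 and 2636. It was 2545 without a filter and 2395 with a filter of 1 CPM in 3 libraries.

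From blastocyst to gastrulation, camera called the liver secreted, yolk lipid, gastrula patterning and keratin lists up and the oocyte and germ plasm lists down. Of the liver secreted genes 58 of 73 tested members rose, 4 fell and 11 did not pass (60 and 4 adjusted over the list alone, camera adjusted p = 2.9e-10). RNA was of whole embryos, so the list's name does not show which tissue expressed these genes. Apolipoprotein A-I (LOC109074514), the main protein of high-density lipoprotein, rose from 0.822 ± 0.553 to 1284 ± 140.5 CPM (log2 change 10.61, SE 0.31, edgeR adjusted p = 9.8e-16). Chordin rose further, from 19.4 ± 7.57 to 1013 ± 64.5 CPM (log2 change 5.70, SE 0.24, edgeR adjusted p = 8.4e-14). The oocyte cell cycle kinase wee2 fell from 389.8 ± 8.002 to 8.65 ± 4.81 CPM (log2 change -5.45, SE 0.29, edgeR adjusted p = 6.4e-12). In all, 30753 features rose and 15441 fell. For protein-coding genes the counts were 16978 and 11714 and for lncRNAs 13754 and 3714.

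Several of the largest rises were from 0 counts at blastocyst. Apolipoprotein A-I-2 (apoa1b) reached 265 ± 29.1 CPM, at least 10950.0-fold higher. An alpha-1-antitrypsin homolog (LOC109112540) reached 244 ± 5.47 CPM, at least 10080.0-fold higher. Apolipoprotein B-100 (LOC109108036) reached 209.7 ± 17.4 CPM, at least 8666-fold higher. The fatty acid carriers fabp2 and fatty acid binding protein 1-B.1 (LOC109095519) rose at least 7857-fold to 190.1 ± 3.56 CPM and at least 7867-fold to 190.4 ± 0.751 CPM. The unnamed lncRNAs MSTRG.20089 and MSTRG.51730 rose at least 2374-fold to 57.5 ± 2.99 CPM and at least 2307-fold to 55.8 ± 10.6 CPM. All of these had edgeR adjusted p = 1.6e-08 or lower. Of the largest falls, both copies of forkhead box H1, the nodal signalling factor, fell. LOC109111626 fell from 171 ± 18.9 to 1.29 ± 0.152 CPM (log2 change -7.04, SE 0.22, edgeR adjusted p = 1.6e-16). LOC109111632 fell from 109.7 ± 29.4 to 0.494 ± 0.224 CPM (log2 change -7.87, SE 0.41, edgeR adjusted p = 1.6e-12). XlCGF52.1-like (LOC109085259), which had risen in the step before, fell from 42.3 ± 10.2 to 0.653 ± 0.592 CPM (edgeR adjusted p = 3.0e-09). The unnamed lncRNA MSTRG.91711 fell from 177 ± 37.3 to 0.439 ± 0.184 CPM (edgeR adjusted p = 1.6e-10).

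Of the mesendoderm and gastrula patterning genes 54 of 60 tested members rose, 2 fell and 4 did not pass (54 and 2 adjusted over the list alone, camera adjusted p = 6.5e-10). The posterior regulator cdx4 rose from 0.941 ± 0.172 to 357 ± 35.4 CPM (log2 change 8.56, SE 0.23, edgeR adjusted p = 1.6e-17). The factor gata6 rose from 4.49 ± 1.65 to 369.7 ± 60.8 CPM, and the mesoderm factor brachyury (LOC109098181) rose from 8.22 ± 2.37 to 205 ± 36.7 CPM (edgeR adjusted p = 1.6e-08 or lower). Of the keratin and epidermis genes 41 of 57 tested members rose, 3 fell and 13 did not pass (41 and 3 adjusted over the list alone, camera adjusted p = 8.3e-08). Keratin 18 (LOC109047943) rose from 66.3 ± 6.28 to 2672 ± 231 CPM (log2 change 5.33, SE 0.12, edgeR adjusted p = 2.3e-18). Of the yolk lipid transport genes 9 of 11 tested members rose, 1 fell and 1 did not pass (9 and 1 adjusted over the list alone, camera adjusted p = 0.0036). Apolipoprotein Eb (LOC109058451) rose from 107 ± 22.97 to 5600.0 ± 392 CPM (edgeR adjusted p = 8.0e-17). Of the Hox genes, which set position along the body axis, 57 of 85 tested members rose, 9 fell and 19 did not pass (57 and 9 adjusted over the list alone, camera adjusted p = 1.0e-04, adjusted p = 0.15 with an estimated correlation). The Hox-B1b copies LOC109058403 and LOC109109931 rose from 0.579 ± 0.331 to 198 ± 24.8 CPM and from 2.95 ± 0.702 to 198 ± 38.8 CPM (edgeR adjusted p = 2.2e-14 or lower), while a Hox-A3a copy (LOC109111780) fell from 2.96 ± 0.3703 to 1.49 ± 0.596 CPM (edgeR adjusted p = 0.0042).

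Of the ribosomal protein genes 135 of 137 tested members rose, 1 fell and 1 did not pass (135 and 1 adjusted over the list alone, camera adjusted p = 2.7e-27, adjusted p = 0.081 with an estimated correlation). The gene rpl10 rose from 104 ± 7.902 to 586 ± 47.1 CPM (log2 change 2.50, SE 0.11, edgeR adjusted p = 2.0e-14). Of the histone genes 128 of 166 tested members rose, 12 fell and 26 did not pass (131 and 12 adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.37 with an estimated correlation). Of the nuclear oxidative phosphorylation genes 103 of 152 tested members rose, 10 fell and 39 did not pass (103 and 10 adjusted over the list alone, camera adjusted p = 3.9e-05, adjusted p = 0.48 with an estimated correlation). The median of the latter list was 0.97 (0.96 with genes at their bound) and turned to -0.00125 under the RPKM denominators, where 53 rose and 37 fell. Of the cartilage, bone and matrix genes 56 of 95 tested members rose, 3 fell and 36 did not pass (56 and 3 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.067 with an estimated correlation). Of the neural genes 63 of 111 tested members rose, 11 fell and 37 did not pass (63 and 11 adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.11 with an estimated correlation). The Notch ligand dla rose from 5.75 ± 1.38 to 84.2 ± 4.76 CPM (edgeR adjusted p = 5.3e-13). Of the skeletal muscle genes 72 of 150 tested members rose, 11 fell and 67 did not pass (64 and 9 adjusted over the list alone, camera adjusted p = 0.069).

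Of the oocyte and maternal genes 17 of 100 tested members rose, 56 fell and 27 did not pass (17 and 56 adjusted over the list alone, camera adjusted p = 2.5e-06). The gene btg4 fell from 298 ± 34.1 to 7.11 ± 6.68 CPM (log2 change -5.34, SE 0.45, edgeR adjusted p = 6.2e-08). Of the germ plasm and piRNA genes 8 of 31 tested members rose, 19 fell and 4 did not pass (8 and 19 adjusted over the list alone, camera adjusted p = 3.1e-05). The gene tdrd6, a tudor gene of germ plasm assembly, fell from 313 ± 31.1 to 24.2 ± 6.495 CPM (log2 change -3.68, SE 0.16, edgeR adjusted p = 1.6e-14). The blastula factors split, with 14 rose and 10 fell of 25, and their median of 0.49 (the same with genes at their bound) turned to -0.14 under library totals. The gene sox19a rose from 34.5 ± 5.76 to 478 ± 42.98 CPM (edgeR adjusted p = 5.4e-14), and pou5f3 rose from 372 ± 12.0 to 463 ± 41.6 CPM (edgeR adjusted p = 0.0087) but was lower at gastrulation under library totals, with a log2 change of -0.35. Cell cycle genes also split, with 37 rose and 40 fell of 103, and their median of 0.04 (the same at the bound) turned to -0.62 under library totals. For these 2 lists, and for eye, leukocyte, innate immunity and hatching enzymes, none called by camera, the test differed in sign from the mean.

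The direction of change at this step depended on the scaling, so changes are relative to TMM factors. Library totals shifted the median of all genes by -0.66 and upper-quartile factors by -0.24 on the log2 scale, and 24110 features rose and 21678 fell under library totals, against 21033 and 24513 under the RPKM denominators. With limma on log2(RPKM + 1), 7543 of 34454 rose and 16969 fell.

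From gastrulation to organ formation, camera called the skeletal muscle, cardiac, cartilage, erythroid and Hox lists up and the gastrula patterning and oocyte lists down. Of the skeletal muscle genes 95 of 150 tested members rose, 13 fell and 42 did not pass (98 and 13 adjusted over the list alone, camera adjusted p = 2.7e-14). Their summed CPM were 16590, 9947 and 10150 in organ formation replicates 1, 2 and 3. The gene actc1b, annotated as an alpha skeletal muscle actin, rose from 0.568 ± 0.389 to 442 ± 18.1 CPM (log2 change 9.46, SE 0.41, edgeR adjusted p = 5.7e-12). Of the erythroid genes 29 of 36 tested members rose, 1 fell and 6 did not pass (29 and 1 adjusted over the list alone, camera adjusted p = 1.4e-12). The embryonic hemoglobin alpha gene LOC109056219 rose to 169 ± 4.84 CPM, 4168-fold, with a counting interval of 1426 to 20210.0 for its 3 counts at gastrulation (edgeR adjusted p = 7.8e-16). Of the gastrula patterning genes 8 of 60 tested members rose, 44 fell and 8 did not pass (9 and 45 adjusted over the list alone, camera adjusted p = 3.5e-11). In all, 19468 features rose and 13745 fell. Of the protein-coding genes 13203 rose and 10634 fell, and of the lncRNAs 6242 rose and 3101 fell.

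Several of the largest rises were again from 0 counts. Calsequestrin-2 (LOC109094822), a calcium store protein of heart muscle, reached 67.1 ± 6.94 CPM, at least 1651-fold higher. The muscle protein kelch-like 41b (LOC109054250) reached 58.2 ± 8.74 CPM, at least 1431-fold higher. The slow troponin I gene tnni1c reached 48.7 ± 3.03 CPM, at least 1197-fold higher. The antimicrobial peptide gene leap2 rose at least 912-fold to 37.1 ± 1.85 CPM. The unnamed lncRNA MSTRG.57110 rose at least 797-fold to 32.4 ± 1.26 CPM. All of these had edgeR adjusted p = 8.5e-12 or lower. Among the largest falls, sox32, a regulator of endoderm, fell from 142 ± 24.3 to 0.0862 ± 0.0619 CPM (log2 change -10.62, SE 0.39, edgeR adjusted p = 4.5e-14). A NEURL1-like ubiquitin ligase (LOC109074496) fell from 756 ± 78.0 to 1.57 ± 0.248 CPM, fbxo32 fell from 347 ± 53.9 to 0.926 ± 0.282 CPM and a homeobox gene of the HESX1 kind (LOC109050959) fell from 38.05 ± 10.6 to 0.0701 ± 0.121 CPM (edgeR adjusted p = 4.6e-11 or lower). The lncRNA MSTRG.57194 fell to 1 count from 15.6 ± 2.26 CPM, 917-fold, with a counting interval of 165 to 36220.0 (edgeR adjusted p = 1.8e-09).

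Of the Hox genes 76 of 85 tested members rose, 2 fell and 7 did not pass (76 and 3 adjusted over the list alone, camera adjusted p = 9.0e-16). The Hox-A3a copy LOC109111780 rose from 1.49 ± 0.596 to 61.8 ± 2.91 CPM (log2 change 5.33, SE 0.27, edgeR adjusted p = 9.3e-13). The Hox-B1b copy LOC109058403 fell from 198 ± 24.8 to 52.2 ± 1.79 CPM (edgeR adjusted p = 6.1e-07). Of the cartilage, bone and matrix genes 66 of 95 tested members rose, 0 fell and 29 did not pass (67 and 1 adjusted over the list alone, camera adjusted p = 4.6e-14). The collagen gene col1a1b rose from 1.36 ± 0.573 to 262 ± 14.6 CPM (log2 change 7.65, SE 0.29, edgeR adjusted p = 1.6e-13). Of the cardiac genes 33 of 46 tested members rose, 0 fell and 13 did not pass (34 and 0 adjusted over the list alone, camera adjusted p = 1.7e-10). A cardiac myosin light chain 1 copy (LOC109107650) rose from 0.0789 ± 0.05201 to 46.1 ± 1.32 CPM (log2 change 9.32, SE 0.21, edgeR adjusted p = 1.0e-15). Of the liver secreted genes 57 of 73 tested members rose, 0 fell and 16 did not pass (58 and 0 adjusted over the list alone, camera adjusted p = 2.2e-16). Apolipoprotein B-100 (LOC109112641) rose from 703 ± 109 to 7559 ± 1612 CPM (edgeR adjusted p = 1.5e-06). Of the neural genes 59 of 111 tested members rose, 14 fell and 38 did not pass (59 and 14 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.054 with an estimated correlation). The glial filament gene LOC109063688 rose from 1.59 ± 0.653 to 245 ± 5.13 CPM (edgeR adjusted p = 4.1e-15). Of the leukocyte genes 14 of 29 tested members rose, 4 fell and 11 did not pass (14 and 4 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.18 with an estimated correlation). The list was not called under library totals, where the camera adjusted p was 0.11.

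Of the hatching enzymes, proteases that dissolve the egg envelope, 13 of 17 tested members rose, 2 fell and 2 did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 0.0067, adjusted p = 0.41 with an estimated correlation). The high choriolytic enzyme LOC109047084 rose from 11.99 ± 1.71 to 1949 ± 109 CPM (log2 change 7.35, SE 1.45, edgeR adjusted p = 0.0016). LOC109061795 rose from 3.99 ± 1.22 to 576 ± 47.7 CPM (edgeR adjusted p = 0.0014). Of the keratin and epidermis genes 31 of 57 tested members rose, 6 fell and 20 did not pass (32 and 6 adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.16 with an estimated correlation). The gene krt4 rose from 509 ± 47.98 to 1109 ± 75.0 CPM and keratin 18 (LOC109047943) fell from 2672 ± 231 to 661 ± 48.7 CPM (edgeR adjusted p = 1.3e-04 or lower). Of the ribosomal protein genes 127 of 137 tested members rose, 1 fell and 9 did not pass (128 and 1 adjusted over the list alone, camera adjusted p = 1.1e-30, adjusted p = 0.067 with an estimated correlation). Of the nuclear oxidative phosphorylation genes 79 of 152 tested members rose, 10 fell and 63 did not pass (81 and 10 adjusted over the list alone, camera adjusted p = 2.9e-04, adjusted p = 0.54 with an estimated correlation).

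Chordin fell from 1013 ± 64.5 to 25.7 ± 3.58 CPM (log2 change -5.30, SE 0.24, edgeR adjusted p = 7.7e-13). Brachyury (LOC109098181) fell from 205 ± 36.7 to 20.4 ± 2.37 CPM (edgeR adjusted p = 2.8e-09). Of the blastula factors 4 of 25 tested members rose, 17 fell and 4 did not pass (4 and 17 adjusted over the list alone, camera adjusted p = 4.1e-05, adjusted p = 0.067 with an estimated correlation). The gene pou5f3 fell from 463 ± 41.6 to 6.501 ± 0.602 CPM (log2 change -6.15, SE 0.13, edgeR adjusted p = 3.3e-18). Of the oocyte and maternal genes 3 of 100 tested members rose, 70 fell and 27 did not pass (3 and 73 adjusted over the list alone, camera adjusted p = 1.6e-18). Of the germ plasm and piRNA genes 4 of 31 tested members rose, 24 fell and 3 did not pass (5 and 25 adjusted over the list alone, camera adjusted p = 2.3e-07). Of the histone genes 5 of 166 tested members rose, 120 fell and 41 did not pass (7 rose, and the number that fell was higher by 4, adjusted over the list alone, camera adjusted p = 1.1e-15, adjusted p = 0.13 with an estimated correlation). Of the cell cycle genes 17 of 103 tested members rose, 59 fell and 27 did not pass (18 and 62 adjusted over the list alone, camera adjusted p = 2.9e-09, adjusted p = 0.15 with an estimated correlation). Cyclin B1 (LOC109080386) fell from 584 ± 61.8 to 110.1 ± 5.29 CPM (log2 change -2.41, SE 0.13, edgeR adjusted p = 3.4e-12). Of the stress response genes 14 rose and 18 fell of 54 (camera adjusted p = 0.23), a balance that turned to 17 and 14 under library totals. The yolk lipid carrier apolipoprotein Eb (LOC109058451) fell from 5600.0 ± 392 to 1573 ± 143 CPM (edgeR adjusted p = 6.6e-10). In its list 5 rose and 3 fell of 11 members tested (camera adjusted p = 0.79).

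Library totals shifted the median of all genes by 0.35 and upper-quartile factors by -0.22 on the log2 scale. Under library totals 24687 features rose and 9620 fell and under the RPKM denominators 23422 and 9187, while under upper-quartile factors slightly fewer rose (16726) than fell (16786).

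From organ formation to hatching, camera called the eye, muscle, cartilage and erythroid lists up and the cell cycle and gastrula patterning lists down. Of the eye genes 101 of 161 tested members rose, 5 fell and 55 did not pass (107 and 7 adjusted over the list alone, camera adjusted p = 1.7e-26). The red-sensitive opsin gene opn1lw1, a cone photopigment, rose from 0.104 ± 0.105 to 5.18 ± 0.642 CPM (log2 change 5.60, SE 0.88, edgeR adjusted p = 3.8e-04). The embryonic hemoglobin alpha gene LOC109056219 rose from 169 ± 4.84 to 1765 ± 282 CPM (log2 change 3.38, SE 0.13, edgeR adjusted p = 6.6e-12). Of the cell cycle genes 2 of 103 tested members rose, 74 fell and 27 did not pass (4 and 76 adjusted over the list alone, camera adjusted p = 8.4e-22). In all, 12086 features rose and 8427 fell. Of the protein-coding genes 9723 rose and 5694 fell, and of the lncRNAs 2347 rose and 2728 fell.

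Lens and muscle genes were among the largest rises from 0 counts. The gamma-crystallin M2 copies LOC109060439, LOC109061066 and LOC109055335, which encode lens proteins, rose at least 694-fold to 35.5 ± 9.68 CPM, at least 535-fold to 27.4 ± 6.13 CPM and at least 405-fold to 20.7 ± 5.18 CPM. The slow troponin I gene tnni4b.1 rose at least 362-fold to 18.5 ± 3.01 CPM, and an immunoglobulin and fibronectin domain gene (LOC109083094) at least 1742-fold to 89.1 ± 37.6 CPM. All of these had edgeR adjusted p = 3.2e-06 or lower. The uncharacterized gene LOC109083011 rose from 2 counts to 64.3 ± 7.08 CPM, 1886-fold, with a counting interval of 522 to 15570.0 (edgeR adjusted p = 1.1e-11). Among the largest falls were T-box and Cdx genes. The Tbx6l copies LOC109113455 and LOC109060377 fell from 22.2 ± 1.56 to 0.439 ± 0.152 CPM and from 20.01 ± 2.54 to 0.572 ± 0.2899 CPM. The gene cdx4 fell from 47.2 ± 6.54 to 1.40 ± 0.278 CPM and a Cdx1 copy (LOC109102671) from 26.9 ± 2.48 to 0.886 ± 0.257 CPM (edgeR adjusted p = 2.6e-09 or lower for each of these 4). The lncRNA MSTRG.33332 fell from 70.97 ± 5.32 to 1.57 ± 0.454 CPM (edgeR adjusted p = 1.8e-10).

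Of the skeletal muscle genes 73 of 150 tested members rose, 11 fell and 66 did not pass (82 and 12 adjusted over the list alone, camera adjusted p = 6.0e-15). Hatching replicate 2 stood apart for this list, with summed CPM of 35470, 64020 and 43370 in replicates 1, 2 and 3. The gene actc1b rose from 442 ± 18.1 to 3490.0 ± 395 CPM (log2 change 2.98, SE 0.27, edgeR adjusted p = 3.2e-07). The titin copy ttn.2 had 1724 ± 755 and 2805 ± 1574 CPM (edgeR adjusted p = 0.27). Of the cartilage, bone and matrix genes 69 of 95 tested members rose, 4 fell and 22 did not pass (72 and 4 adjusted over the list alone, camera adjusted p = 1.1e-12). The gene col1a1a rose from 318 ± 30.9 to 1677 ± 77.2 CPM (log2 change 2.40, SE 0.34, edgeR adjusted p = 8.7e-05). Of the neural genes 61 of 111 tested members rose, 10 fell and 40 did not pass (67 and 10 adjusted over the list alone, camera adjusted p = 2.3e-10). The neuronal RNA-binding gene ELAV-like 4 (LOC109068983) rose from 9.94 ± 1.58 to 109.5 ± 5.501 CPM (log2 change 3.46, SE 0.34, edgeR adjusted p = 7.0e-07). Of the erythroid genes 19 of 36 tested members rose, 1 fell and 16 did not pass (21 and 1 adjusted over the list alone, camera adjusted p = 5.2e-08). Of the leukocyte genes 14 of 29 tested members rose, 2 fell and 13 did not pass (14 and 2 adjusted over the list alone, camera adjusted p = 2.2e-04). Of the cardiac genes 14 of 46 tested members rose, 3 fell and 29 did not pass (15 and 4 adjusted over the list alone, camera adjusted p = 0.0067). The myeloperoxidase gene LOC109052003, a granulocyte enzyme, rose from 8.55 ± 0.616 to 48.05 ± 6.62 CPM (edgeR adjusted p = 2.6e-05). The eye list holds phosducin-like genes of general protein folding, and of these pdcl3 had 236 ± 12.5 and 222 ± 28.3 CPM (edgeR adjusted p = 0.63).

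Of the nuclear oxidative phosphorylation genes 62 of 152 tested members rose, 0 fell and 90 did not pass (68 and 1 adjusted over the list alone, camera adjusted p = 2.2e-08, adjusted p = 0.30 with an estimated correlation). The gene atp5f1 rose from 193 ± 8.19 to 337 ± 39.9 CPM (edgeR adjusted p = 4.6e-05). Of the pancreas and gut enzyme genes 18 of 76 tested members rose, 4 fell and 54 did not pass (18 and 4 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.49 with an estimated correlation). That call ended, at a camera adjusted p of 0.064, when members outside the list's name were left out, an alternative chosen after seeing the data. Of the Hox genes 4 rose and 11 fell of 85 (camera adjusted p = 0.22), which turned to 12 and 3 under the RPKM denominators. The hatching enzyme LOC109047084 did not pass the test, with 1949 ± 109 and 3442 ± 309 CPM (edgeR adjusted p = 0.63). In the list 1 of 17 tested members rose, 1 fell and 15 did not pass (1 and 1 adjusted over the list alone, camera adjusted p = 0.98). The list's summed CPM were 4010, 3923 and 4397 in organ formation replicates 1, 2 and 3 and 7077, 6384 and 7411 at hatching, without overlap. The fit shares 1 error estimate per gene over all 18 libraries, so spread among the larva libraries enters the gene tests of this step. A missing call here does not show that levels stayed equal.

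Ribonucleotide reductase M2 (LOC109112777), which makes deoxynucleotides for replication, fell from 426 ± 4.82 to 159 ± 16.97 CPM (log2 change -1.42, SE 0.11, edgeR adjusted p = 3.2e-09). Of the histone genes 7 of 166 tested members rose, 80 fell and 79 did not pass (7 and 88 adjusted over the list alone, camera adjusted p = 8.7e-12, adjusted p = 0.20 with an estimated correlation), with summed CPM of 25250, 17600 and 26510 in hatching replicates 1, 2 and 3. The histone H2A copy LOC109060821 fell from 2877 ± 145 to 1759 ± 328 CPM (edgeR adjusted p = 6.2e-05). Of the mesendoderm and gastrula patterning genes 6 of 60 tested members rose, 30 fell and 24 did not pass (6 and 33 adjusted over the list alone, camera adjusted p = 1.7e-09). Of the blastula factors 4 of 25 tested members rose, 15 fell and 6 did not pass (4 and 16 adjusted over the list alone, camera adjusted p = 7.4e-06). Of the oocyte and maternal genes 8 of 100 tested members rose, 40 fell and 52 did not pass (8 and 41 adjusted over the list alone, camera adjusted p = 2.6e-06). Of the germ plasm and piRNA genes 0 of 31 tested members rose, 11 fell and 20 did not pass (0 and 11 adjusted over the list alone, camera adjusted p = 2.3e-04). The gene sox19a fell from 288 ± 22.6 to 122 ± 27.99 CPM (log2 change -1.24, SE 0.16, edgeR adjusted p = 4.0e-06). The keratin and yolk lipid lists were not called (camera adjusted p = 0.94 and camera adjusted p = 0.82), and in both the test differed in sign from the median.

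Upper-quartile factors shifted the median of all genes by -0.13 on the log2 scale, and 10499 features rose and 11026 fell under them. Under the RPKM denominators 18664 rose and 2872 fell. With a 2-fold minimum the lncRNAs numbered 2193 that rose and 2180 that fell.

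From hatching to the larva, camera called the eye, cartilage and muscle lists up, though most members of each did not pass, and the histone, cell cycle and erythroid lists down. Of the eye genes 47 of 161 tested members rose, 2 fell and 112 did not pass (52 and 2 adjusted over the list alone, camera adjusted p = 1.2e-17). The cone arrestin gene LOC109052315 rose from 4.81 ± 1.21 to 269.7 ± 63.03 CPM (log2 change 5.81, SE 0.24, edgeR adjusted p = 1.1e-09). Of the histone genes 1 of 166 tested members rose, 109 fell and 56 did not pass (2 and 121 adjusted over the list alone, camera adjusted p = 1.7e-45). Of the erythroid genes 0 of 36 tested members rose, 18 fell and 18 did not pass (0 and 30 adjusted over the list alone, camera adjusted p = 2.5e-15). The hemoglobin beta gene LOC109099560 fell from 698 ± 115 to 24.6 ± 17.4 CPM (log2 change -4.82, SE 0.51, edgeR adjusted p = 4.9e-05), with 41.3, 25.9 and 6.57 CPM in replicates 1, 2 and 3. In all, 3686 features rose and 4248 fell, while 1992 rose and 3179 fell without larva replicate 3. Of the protein-coding genes 3329 rose and 3688 fell, and of the lncRNAs 347 rose and 557 fell.

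Larva replicate 3 correlated with the other larva libraries at 0.945 to 0.949 on log2 CPM, against 0.979 between those 2 and 0.958 to 0.980 within other stages. Leaving out each library in turn was planned, and giving the counts without this one beside the results was chosen after seeing the data. The summed CPM of the pancreas and gut enzyme list were 532, 541 and 4908 in larva replicates 1, 2 and 3, and of the hatching enzyme list 1689, 1439 and 474. In the same order they were 28630, 29440 and 20400 for the liver secreted list, 3626, 4181 and 5613 for the eye list, 869, 815 and 568 for the Hox list and 6855, 7217 and 9848 for the nuclear oxidative phosphorylation list.

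Several of the largest rises were of genes with their highest level in that library. The elastase gene cela1 rose from 0.604 ± 0.396 to 226 ± 375 CPM (log2 change 8.52, SE 2.04, edgeR adjusted p = 0.031), with 7.36, 11.96 and 659.9 CPM in replicates 1, 2 and 3, and without replicate 3 its test gave log2 change 3.97, edgeR adjusted p = 2.3e-04. Carboxypeptidase A2 (LOC109064543), a pancreatic protease, rose from 2 counts to 46.3 ± 78.1 CPM, 2155-fold, with a counting interval of 597 to 17800.0 (edgeR adjusted p = 0.02), and measured 1.12, 1.298 and 136 CPM in replicates 1, 2 and 3. Without replicate 3 its test gave log2 change 5.52, edgeR adjusted p = 0.027. Syncollin (sycn), a protein of zymogen granules, measured 4.92, 5.75 and 133.9 CPM in replicates 1, 2 and 3, and the fast troponin I gene LOC109090835 3.099, 2.67 and 40.8 CPM in replicates 1, 2 and 3 (edgeR adjusted p = 0.043 or lower with all libraries). Without replicate 3 their tests gave log2 change 5.55, edgeR adjusted p = 0.0012 and log2 change 6.28, edgeR adjusted p = 6.8e-04. Of the pancreas and gut enzyme genes 16 of 76 tested members rose, 2 fell and 58 did not pass (26 and 2 adjusted over the list alone, camera adjusted p = 3.6e-07, adjusted p = 0.12 with an estimated correlation). Without larva replicate 3, 8 rose and 3 fell. In the same list fabp2 fell from 442 ± 19.4 to 222 ± 33.3 CPM (log2 change -0.99, SE 0.10, edgeR adjusted p = 3.7e-06). Trypsin (prss59.1) and chymotrypsin B (ctrb.3) had 0.202 ± 0.0956 and 137 ± 236 CPM and 0.108 ± 0.0385 and 129.9 ± 223 CPM (edgeR adjusted p = 0.065 and 0.057). These measured 1.01, 1.16 and 409.8 CPM in replicates 1, 2 and 3 (without replicate 3, log2 change 2.37, edgeR adjusted p = 0.30) and 1.16, 1.19 and 387 CPM in replicates 1, 2 and 3 (without replicate 3, log2 change 3.38, edgeR adjusted p = 0.067).

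Without larva replicate 3, 36 rose and 2 fell among eye genes. The gene opn1lw1 rose from 5.18 ± 0.642 to 380.5 ± 236 CPM (log2 change 6.20, SE 0.48, edgeR adjusted p = 8.3e-06), with 219, 272 and 651 CPM in replicates 1, 2 and 3 (without replicate 3, log2 change 5.54, edgeR adjusted p = 5.6e-10). Of the cartilage, bone and matrix genes 41 of 95 tested members rose, 2 fell and 52 did not pass (53 and 4 adjusted over the list alone, camera adjusted p = 8.3e-11), and 29 rose and 2 fell without larva replicate 3. Of the skeletal muscle genes 42 of 150 tested members rose, 5 fell and 103 did not pass (53 and 7 adjusted over the list alone, camera adjusted p = 2.9e-09), and 28 rose and 5 fell without larva replicate 3. Of their members, col1a1a had 1677 ± 77.2 and 2396 ± 479 CPM (edgeR adjusted p = 0.40) and actc1b 3490.0 ± 395 and 5746 ± 1227 CPM (edgeR adjusted p = 0.083). Of the neural genes 32 of 111 tested members rose, 22 fell and 57 did not pass (50 and 28 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.12 with an estimated correlation), and 25 rose and 20 fell without larva replicate 3. The call ended without hatching replicate 2 or larva replicate 3. The Notch ligands dla and dlb fell from 148 ± 22.5 to 37.6 ± 11.1 CPM and from 184 ± 24.1 to 36.5 ± 11.6 CPM (edgeR adjusted p = 8.6e-07 or lower). Of the stress response genes 12 of 54 tested members rose, 6 fell and 36 did not pass (23 and 8 adjusted over the list alone, camera adjusted p = 0.008, adjusted p = 0.12 with an estimated correlation), and 11 rose and 6 fell without larva replicate 3. Of the nuclear oxidative phosphorylation genes 7 of 152 tested members rose, 0 fell and 145 did not pass (1 and 0 adjusted over the list alone, camera adjusted p = 7.4e-08, adjusted p = 0.33 with an estimated correlation), and 1 rose and 0 fell without larva replicate 3.

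Histone H2A (LOC109060821) fell from 1759 ± 328 to 871 ± 87.2 CPM (log2 change -1.01, SE 0.12, edgeR adjusted p = 7.4e-06), and 0 rose and 115 fell among histone genes without larva replicate 3. Of the cell cycle genes 1 of 103 tested members rose, 60 fell and 42 did not pass (1 and 67 adjusted over the list alone, camera adjusted p = 1.1e-30), and 0 rose and 61 fell without larva replicate 3. The spindle motor KIF11 (LOC109106936) fell from 183 ± 21.97 to 95.5 ± 1.44 CPM (log2 change -0.94, SE 0.10, edgeR adjusted p = 2.3e-06). Among erythroid genes 0 rose and 20 fell without larva replicate 3. Of the Hox genes 0 of 85 tested members rose, 15 fell and 70 did not pass (0 and 17 adjusted over the list alone, camera adjusted p = 8.7e-07, adjusted p = 0.08 with an estimated correlation), and 0 rose and 6 fell without larva replicate 3. Of the blastula factors 1 of 25 tested members rose, 10 fell and 14 did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 1.4e-04, adjusted p = 0.082 with an estimated correlation), and 1 rose and 8 fell without larva replicate 3. Of the germ plasm and piRNA genes 0 of 31 tested members rose, 6 fell and 25 did not pass (0 and 7 adjusted over the list alone, camera adjusted p = 0.0016), and 0 rose and 1 fell without larva replicate 3. Of the ribosomal protein genes 0 of 137 tested members rose, 1 fell and 136 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.008, adjusted p = 0.73 with an estimated correlation). The call ended under library totals and without hatching replicate 1 or 3 or larva replicate 1 or 2. DESeq2 size factors turned this balance to 1 rose and 0 fell. The hatching enzymes had wide spreads: 1 of 17 tested members rose, 1 fell and 15 did not pass (2 and 10 adjusted over the list alone, camera adjusted p = 2.9e-04, adjusted p = 0.26 with an estimated correlation). Without larva replicate 3, 1 rose and 10 fell. LOC109047084 had 3442 ± 309 and 474 ± 413 CPM (edgeR adjusted p = 0.16), with 767, 653 and 1.896 CPM in replicates 1, 2 and 3. Without replicate 3 it fell (log2 change -2.30, edgeR adjusted p = 7.7e-09).

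Further large falls were of 3 copies of an immunoglobulin superfamily gene of the DCC subclass. LOC109075549 fell from 231 ± 34.6 to 12.4 ± 10.4 CPM, LOC109073075 from 76.2 ± 6.82 to 3.65 ± 2.85 CPM and si:ch211-57n23.4 from 123.7 ± 15.1 to 6.46 ± 4.15 CPM (edgeR adjusted p = 4.8e-04 or lower). The lncRNA LOC109047757 fell from 11.3 ± 1.46 to 0.464 ± 0.249 CPM (log2 change -4.55, SE 0.25, edgeR adjusted p = 1.1e-09) and MSTRG.55592 rose from 1 count to 12.3 ± 12.4 CPM, 1148-fold, with a counting interval of 206 to 45340.0 (edgeR adjusted p = 2.0e-05). The latter measured 3.37, 7.12 and 26.5 CPM in replicates 1, 2 and 3, and without replicate 3 its test gave log2 change 8.41, edgeR adjusted p = 4.0e-05. Liver secreted genes were not called (10 rose and 7 fell of 73, camera adjusted p = 0.61, and 4 rose and 9 fell without larva replicate 3), and in this list, and in the cardiac, leukocyte and keratin lists, median and mean differed in sign.

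Which of rises and falls led turned with the setting. Under library totals 4333 features rose and 3157 fell, under the RPKM denominators 3462 and 1883, with DESeq2 5772 and 4509 and with a 2-fold minimum 2783 and 1042. It turned as well with only the 2 stages in the fit (7726 and 5053), a filter of 1 CPM in 3 libraries (4104 and 3449), no filter (3383 and 3363) and limma on log2(RPKM + 1) (4611 and 3394). The counts also rest on single hatching libraries: 1725 features rose and 2488 fell without hatching replicate 1, 2447 rose without replicate 2, and 1712 rose and 2375 fell without replicate 3.

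**Figure D2:**
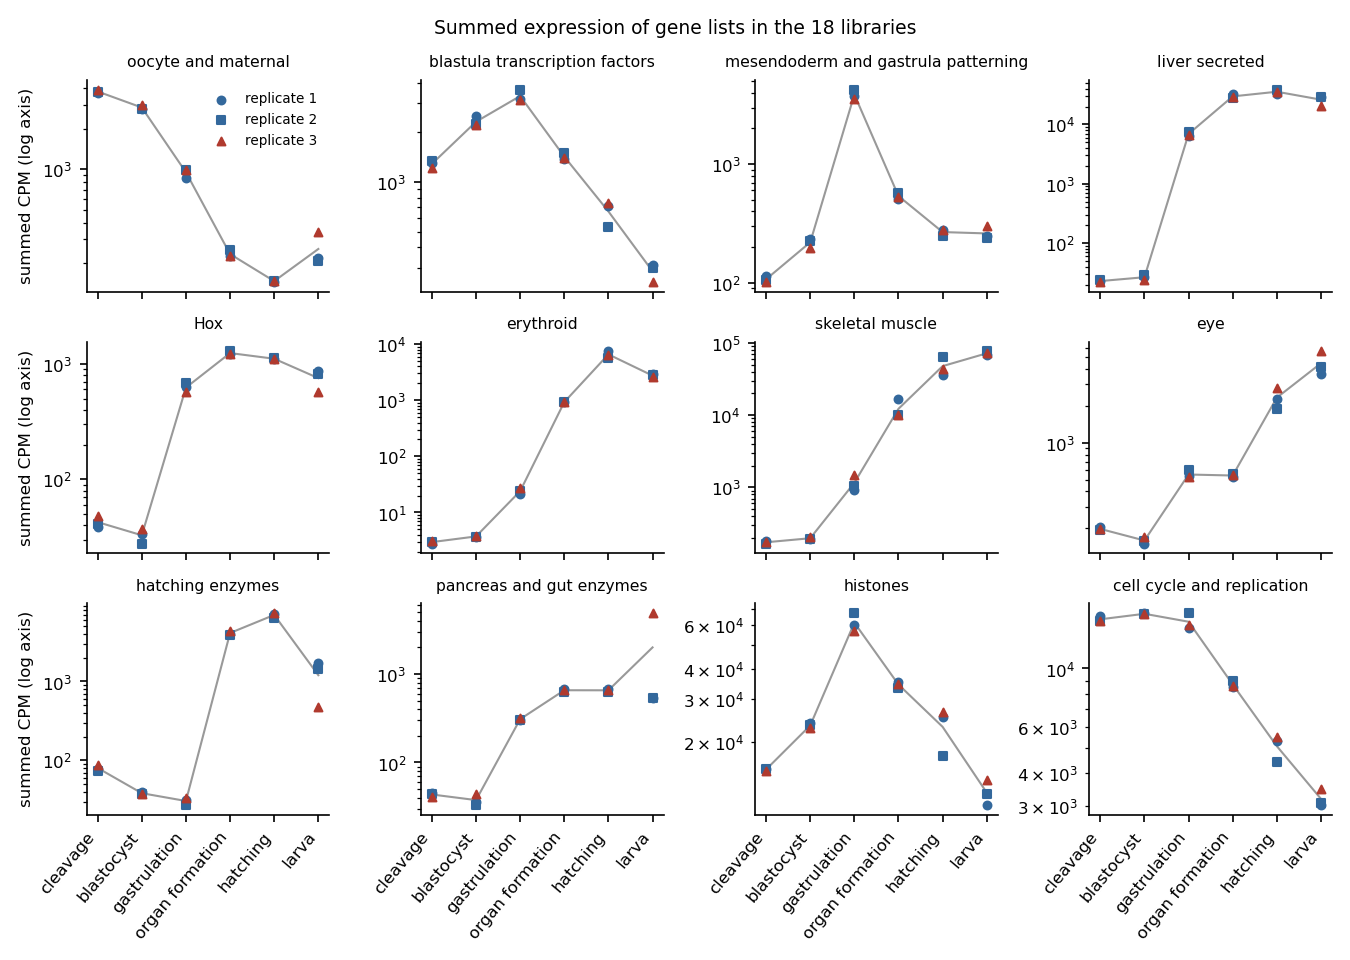
Summed CPM (log axis) of 12 gene lists in each of the 18 libraries, with replicates 1, 2 and 3 marked apart and lines through the stage means. The oocyte and maternal list falls to organ formation, the liver, erythroid and muscle lists climb over several stages, and larva replicate 3 stands apart for pancreas and gut enzymes (4908 CPM against 532 and 541) and hatching enzymes.

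The number of genes detected at equal depth had its lowest mean at cleavage and its highest in the larva. After thinning every library to 16326813 counts, 34586 ± 365 features (mean ± SD, n = 3) had 10 or more counts at cleavage, 37453 ± 480.2 at blastocyst, 40902 ± 1596 at gastrulation, 50345 ± 904 at organ formation, 51807 ± 1581 at hatching and 54283 ± 1288 in the larva. Protein-coding genes detected went from 26615 ± 96.5 at cleavage to 37484 ± 190.2 in the larva. LncRNAs detected went from 7943 ± 300.2 at cleavage to a highest mean of 17331 ± 651 at organ formation, and measured 16234 ± 1260 at hatching and 16751 ± 1441 in the larva. The stage of the highest lncRNA mean turned with the counting rule: with 1 or more counts it was the larva (29754 against 28882 at organ formation) and without thinning it was hatching (20848 against 18786). The lncRNA share of counts was 5.25 ± 0.491% at cleavage, 6.36 ± 0.383% at blastocyst, 9.74 ± 0.979% at gastrulation, 11.6 ± 0.679% at organ formation, 8.99 ± 1.03% at hatching and 9.01 ± 1.10% in the larva. As a share of summed RPKM, which allows for length, it was 14.8 ± 1.003% at cleavage and 19.6 ± 0.717% at organ formation, a smaller ratio. LncRNAs with a StringTie name only held 4.17 ± 0.435% of counts at cleavage and 10.2 ± 0.669% at organ formation.

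With 3 libraries against 3 the 2-sided exact permutation test cannot go below p = 0.1, and chance gives stages that do not overlap in 10% of such comparisons. The test gave this lowest p for each step of the protein-coding count, for the first 3 steps of the lncRNA count and of the count of all features, and for the first 4 steps of the lncRNA share. For the count of all features the exact p was 0.3 from organ formation to hatching and 0.2 from hatching to the larva. The exact test gave p = 0.3 for the lncRNA count from organ formation to hatching and 0.9 from hatching to the larva, where the share gave an exact p of 1.0. The 10 most abundant features held 1.303 ± 0.111% of counts at cleavage and 4.75 ± 0.374% in the larva.

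**Figure D3:**
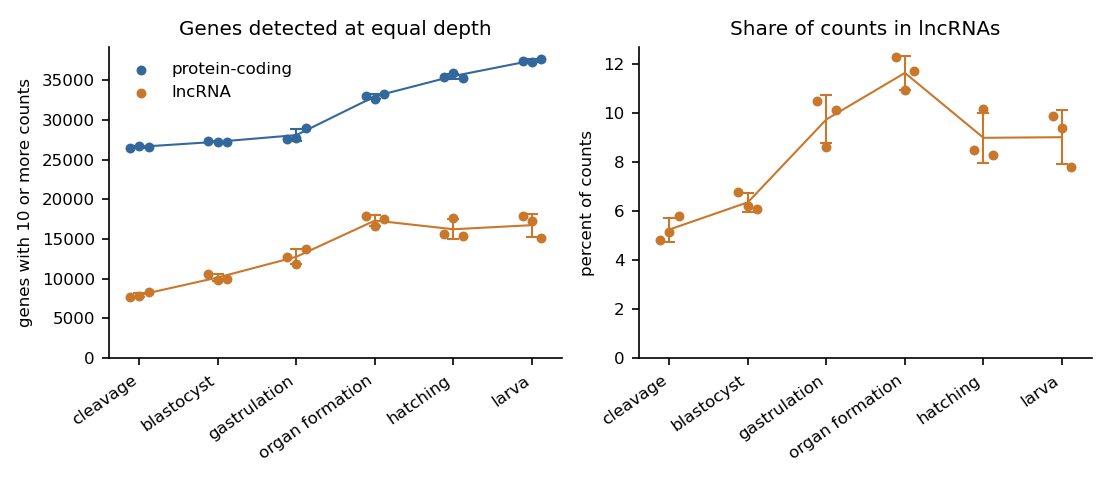
Left, protein-coding genes and lncRNAs with 10 or more counts in each library after thinning to 16326813 counts, and right, percent of counts in lncRNAs, with points for libraries and lines and bars for the mean and SD of 3 libraries per stage. The lncRNA share has its highest mean, 11.6%, at organ formation.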

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

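The alternatives that thinned the counts, left out list members outside the name, left out a library of a stage not compared, led with counts without larva replicate 3 or used the library denominators of the RPKM were chosen after seeing the data, and the others were planned. Where no reason is given, the cause was not tested.

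At an adjusted p under 0.01, fewer features pass by construction: 6736 rose and 2450 fell from cleavage to blastocyst, 5220 fell from organ formation to hatching, and 1776 rose and 2322 fell from hatching to the larva. With a 2-fold minimum, again stricter by construction, 1867 fell to blastocyst, 9033 to organ formation, 4130 to hatching and 1042 to the larva, where 2783 rose, so that the balance turned. To blastocyst 2545 fell without a filter and 2395 with a filter of 1 CPM in 3 libraries. With only the 2 stages in the fit, 5939 rose to blastocyst, 12716 fell to hatching and 7726 rose to the larva. With DESeq2 5772 rose to the larva.

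With limma on log2(RPKM + 1), 1821 rose and 6857 fell to blastocyst and 7543 rose and 16969 fell to gastrulation, so that both balances turned, while 12302 rose and 7488 fell to organ formation, 2717 fell to hatching, and the genes differing among the 6 stages numbered 33867. With log2(RPKM + 0.1) these were 2282 that rose and 5611 that fell to blastocyst, 8585 that rose to gastrulation, 7929 that fell to organ formation, 2667 that fell to hatching, 2815 that fell to the larva and 33813 differing among the 6 stages. With the RPKM denominators in edgeR, 24513 fell to gastrulation, 18664 rose and 2872 fell to hatching, and 1883 fell to the larva.

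Leaving out 1 library of the 2 stages compared gave 2289 to 4173 falls to blastocyst, lowest without cleavage replicate 2, and 1712 to 3171 rises and 2375 to 3932 falls to the larva, both lowest without hatching replicate 3. Fewer libraries were tested in each. Leaving out 1 library of another stage gave 2564 to 5092 falls to blastocyst, lowest without gastrulation replicate 2 and highest without larva replicate 3, and 3381 to 4449 rises and 3295 to 4778 falls to the larva. The other counts of calls stayed within 1.5 times their value when 1 library was left out.

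Some named genes higher at gastrulation than blastocyst turned under library totals, with log2 changes of -0.00238 for LOC109045954 (109045954), gastrulation vs blastocyst, -0.29 for LOC109046005, -0.35 for pou5f3, -0.19 for atp5b, -0.64 for LOC109109195 and -0.49 for LOC109112777. With limma on log2(RPKM + 1) they were -0.34, -0.60, -0.66, -0.52, -0.91 and -0.81 in the same order, and top2a (-0.14), dusp1 (-0.27) and LOC109082942 (-0.10) turned too, as did dlb (109059730), gastrulation vs blastocyst, at -0.0521. Under the same setting fabp2 (109093321), hatching vs organ formation, turned to 0.0909. Of the values of named genes, 507 kept direction and call under library totals, 508 under DESeq2, 518 under upper-quartile factors, 508 without a filter and 404 with log2(RPKM + 1). When 1 library of the stages compared was left out, 52 of these values lost their call in at least 1 such setting and 29 gained one.

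With an estimated correlation between genes, 3 lists were called up and 0 down to blastocyst, 4 up to gastrulation, 6 up and 3 down to organ formation, and 3 up and 4 down to the larva. Fry, which does not compare a list with other genes, called 9 lists up to blastocyst and 17 to gastrulation. It turned liver secreted (adjusted p = 0.050), neural (adjusted p = 0.0058) and stress response genes (adjusted p = 0.00024) up at the step to blastocyst, and eye (adjusted p = 3.2e-05) and innate immune genes (adjusted p = 3.4e-05) up at the step to gastrulation. With members taken by symbol alone, which leaves fewer members, 3 lists were called up to blastocyst, 5 up to gastrulation, 5 up and 3 down to hatching and 5 down to the larva. Without members outside the name 112 of the list tests kept their call, 1 was gained (oocyte genes from hatching to the larva) and 2 were lost (germ plasm genes to blastocyst and pancreas enzymes to hatching). Leaving out 1 library of the stages compared ended 3 list calls: germ plasm genes to blastocyst, and neural and ribosomal protein genes to the larva. It gained 4: innate immune genes to blastocyst and to the larva, skeletal muscle genes to gastrulation and ribosomal protein genes to hatching. Under library totals leukocyte genes to organ formation and ribosomal protein genes to the larva lost their call, and cell cycle and skeletal muscle genes to gastrulation gained one.

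The genes detected per library also moved with the counting rule. Without thinning, the values were -266.0 for genes detected per library, all features, larva vs hatching, 2062 for genes detected per library, lncRNA, hatching vs organ formation and -1017 for genes detected per library, lncRNA, larva vs hatching. With a minimum of 1 count, lncRNAs detected differed by 519.3 from organ formation to hatching. Leaving out 1 library gave -48.2 to 1329 lncRNAs from hatching to the larva and -0.402 to 0.642 percentage points for share of counts in lncRNAs, larva vs hatching, each lowest without larva replicate 1.

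With the replicate number as a block, 10009 rose and 4094 fell to blastocyst, 30291 and 15093 to gastrulation, 18671 and 13268 to organ formation, 11428 and 7791 to hatching and 3020 and 3878 to the larva, with 64304 as the count of genes differing among the 6 stages. Of the named gene values 528 kept their call, 3 gained and 5 lost it, and all 115 list tests kept theirs. Deviations of libraries with the same number correlated at -0.085 to 0.085 across genes, and not every library correlated best with its own number, so the numbers do not pair the libraries. Low counts limited recovery in the simulation: edgeR recovered 29% of the 2-fold changes made and 60% among features with over 100 counts.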

Other observations

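The tests on larva replicate 3 were chosen after its correlations were seen, and the other tests were planned before their results were seen. Innate immune genes were the 1 list that camera called at no step in the main test (camera adjusted p = 0.079 to blastocyst, camera adjusted p = 0.77 to gastrulation, camera adjusted p = 0.095 to organ formation, camera adjusted p = 0.093 to hatching and camera adjusted p = 0.057 to the larva). At the step to organ formation 66 of its 196 tested members rose, 25 fell and 105 did not pass, with the same 66 and 25 adjusted over the list alone. Complement C3 (LOC109059061), the central protein of the complement cascade, fell from 25.3 ± 2.98 to 8.09 ± 0.961 CPM from cleavage to blastocyst (log2 change -1.65, SE 0.32, edgeR adjusted p = 0.0016) and rose from 8.81 ± 3.399 to 532 ± 47.04 CPM from gastrulation to organ formation (log2 change 5.88, SE 0.38, edgeR adjusted p = 2.1e-09). The other most abundant members of the list are outside its name, and of them c37h6orf62 rose from 19.2 ± 1.84 to 242 ± 24.1 CPM from blastocyst to gastrulation (edgeR adjusted p = 1.4e-15).

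Hox genes of the 9 to 13 paralogue groups (36 genes) had a median of 0.515 CPM at gastrulation and 13.1 CPM at organ formation, those of groups 5 to 8 (22 genes) 3.26 and 10.7 CPM and those of groups 1 to 4 (27 genes) 1.03 and 14.9 CPM. One hypothesis is that genes of higher number rise later, in line with the temporal order known for Hox clusters. Across 85 genes, which are not independent replicates, paralogue number and the log2 change from gastrulation to organ formation had a Spearman rho of 0.223 (permutation p = 0.042, 0.058 after Benjamini-Hochberg adjustment over 3 comparisons, so that it fails the correction) and a Pearson r of 0.273. From blastocyst to gastrulation rho was -0.36 (permutation p = 0.0007, adjusted 0.0021) and Pearson r -0.348, and from organ formation to hatching rho was 0.207 (permutation p = 0.058, adjusted 0.058) and Pearson r 0.317.

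More features rose than fell from blastocyst to gastrulation (66.6% of calls with TMM factors). Unequal depth and low-count features are argued against as the whole cause: the share was 59.96% with all libraries thinned to 1 total and 62.9% among the 34396 calls with a mean of 1 CPM or more. The scaling stays open, since the share was 52.7% under library totals and 46.2% under the RPKM denominators. Without a spike-in the direction of the whole transcriptome may therefore be set by the scaling, and a true rise in the number of transcribed genes stays open as the biological explanation.

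Larva replicate 3 stands apart from the other larva libraries. A swap with another stage is argued against by its mean correlation of 0.947 with them, against 0.903 with the hatching libraries, and depth by its lowest correlation of 0.945 after thinning, where no library of another stage was below 0.962. That it was further along in development is a candidate explanation: its difference from 1 larva library correlated with the difference of the other larva library from hatching, at 0.129 in 1 order and 0.199 in the other, across genes, which are not independent replicates. The summed CPM of lists that camera called down from hatching to the larva did not all fit this: in larva replicates 1, 2 and 3 they were 11060, 12310 and 14000 for histones and 3019, 3090 and 3474 for the cell cycle list, highest in replicate 3. The correlations are small, and no label gives the age of single libraries. Other differences between its animals and those of the other libraries were not tested and stay open.

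Copies of duplicated genes had alike profiles. Over 4903 pairs of features with the same name, the median correlation of the 6 stage means was 0.864, against 0.156 to 0.289 in 1000 sets of random pairs of like expression. Shared regulation may account for this, and so may reads shared between copies, which the test does not separate. In 685 pairs (13.97%) the correlation was below 0, and so it was in 242 of the 2551 pairs with both copies at 10 CPM or more in some stage.

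LncRNAs were tested for being more stage-restricted than protein-coding genes. Their median tau, an index from 0 for even to 1 for single-stage expression, was 0.592 against 0.423, but at matched expression the difference was -0.0212 (resampling genes, -0.0245 to -0.0169). The sign depended on the expression bin: lncRNA tau was higher in 15 of 40 bins, with bin differences from -0.0609 to 0.164. Expression level may account for the unmatched difference, and an effect of class at some levels stays open. Protein-coding genes that rose from cleavage to blastocyst (5216 genes) were tested for being short. The median length implied by the RPKM was 1.04 times that of unchanged genes of like counts (1.02 to 1.06), and they were shorter in 15 of 40 bins. This argues against a shorter length of the kind the RPKM used, for protein-coding genes. Whether that length counts introns is not given in the sources used here, so the test cannot decide on transcripts before splicing. LncRNAs were not part of this test.

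Among the 80 regroupings of the 18 libraries, real grouping included, 1 gave as many differing features as the stages, the stages themselves (64874, highest other 3246). Other regroupings mix libraries of different stages, which widens the spread within groups, so few calls were to be expected from them. The libraries were made from pooled RNA, so the regroupings cannot exclude chance differences between pools. For the single steps the 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 of 10 splits gave as many calls, the real one, with 15479 calls and a highest other of 237 for blastocyst, 46194 and 1 for gastrulation, 33213 and 0 for organ formation, 20513 and 0 for hatching, and 7934 and 0 for the larva.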
